A study of Homo sapiens with 20 samples.

How the data were processed

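HEK293T cells were treated with the Aurora-A inhibitor MLN8237 or its solvent DMSO for 24 hours, or were transfected with siRNAs for 48 hours, and stranded mRNA libraries were sequenced, per the labels' protocols. The 20 samples form 10 groups of 2. MLN8237 was compared with DMSO. Depletions of SRSF1, SRSF2, SRSF7 and SF3B5 were compared with a first non-targeting group (siNT1), and depletions of SRSF3 and RBM39 with a second (siNT2). Nothing in the labels says whether the 2 samples of a group came from separate cultures.

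The authors deposited 7 tables of differential splicing events, whose names point to VAST-TOOLS. Per the file headers, each table gives a gene, an event identifier, an event length, and the average percent spliced in (PSI) of the control and of the treated group as percent values made by the authors, with their difference in percentage points. Per the submitters' processing notes, cutadapt, Bowtie and the hg38 build were used; their versions, the read counts behind each PSI and the rule by which events were listed are not given in the sources used here. The smallest absolute change in the tables was just above 15 points. Because only group averages were analysed, no SD or n stands behind a single PSI value here, the depth per event is unknown, and no event was tested again. With 2 samples against 2, an exact two-sided permutation test cannot go below p = 0.333. Expression of the depleted or inhibited genes was not analysed here, so the depletions themselves were not checked.

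Event types were read from the event identifiers, with exons of up to 27 bases counted as microexons and longer ones as cassette exons. An exon or intron with a lower PSI is more often skipped or more often spliced out. For alternative splice sites, all listed events of the 7 tables had a higher PSI in the treated group, so their direction carries no information, and tests of direction are given for exons and introns. That restriction was chosen after the data were examined.

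Directions were tested with the exact binomial test, over 42 tests. The listing threshold limits direction by the control PSI. An exon close to full inclusion could only be listed as lower, and an intron almost never retained only as higher. An even split is therefore not the expectation for every list, and no test matched for control PSI was made. Shares of event types were tested with Fisher's exact test, each table against events found only in the other tables, over 35 tests. Sharing of events between 2 tables was tested with Fisher's exact test over the events of the remaining depletion tables, which makes the background independent of either table's own threshold. All tests were two-sided with Benjamini-Hochberg adjustment within each family, and a level of 0.05. Odds ratios have Woolf 95% intervals, with 0.5 added to each cell when a cell was empty, and percentages have exact Clopper-Pearson 95% intervals. Medians have bootstrap 95% intervals from 10000 resamples of events. These p-values and intervals describe events, which are not independent replicates, and do not measure the spread between cultures.

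Before the data were examined, 11 gene lists with 711 genes were fixed. They cover SR proteins, hnRNPs and other splicing regulators, the core spliceosome, splicing kinases and phosphatases, mitosis with centrosome and spindle, cell cycle control, apoptosis, DNA damage response and repair, nonsense-mediated decay, 3' end processing and export, and chromatin regulators. For these, Fisher's exact test compared each list with the 7111 genes that had an event in any table, over 77 tests. Of 7112 symbols in the tables, 6747 were current, 267 were matched through a RefSeq synonym and 98 had no match. The genes named were chosen by a rule fixed at the same time. It takes the 12 genes with the highest and the 12 with the lowest change for MLN8237, 6 and 6 for each depletion, up to 8 genes of the fixed lists per table, up to 12 genes per depletion shared with MLN8237, and events in the inhibited or depleted genes. Some of the events that this rule selects are not reported here. Exon and intron coordinates are not the authors'. They come from GENCODE release 29 on GRCh38 and are given only where the gene has a single annotated exon or intron of the event's length.

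For pairs of depletions with the same control libraries, unchanged groups were simulated from the differences between siNT1 and siNT2. The overlap, list and direction tests were tested on simulated data with 200 repeats. With 92 events, a true odds ratio of 4 was recovered as medians from 3.84 for the SRSF1 table to 4.10 for the RBM39 table, and a true odds ratio of 1 passed in 1.5% to 3.5% of repeats. A true same-direction share of 0.8 passed the unadjusted level in 68% of repeats at the 16 events shared with SRSF2 and in 98% at the 45 shared with RBM39. Alternatives covered a stricter threshold of 25 points, omission of retained introns, 1 event per gene, other backgrounds, matching by gene symbol, omission of microexons and cassette exons alone. Alternatives added after the data were examined were exons and introns alone, events with a control PSI of 20 to 80, and equal-sized strata of annotated exon number, tested with the continuity-corrected Mantel-Haenszel chi-squared test over genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.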

Results

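Alternative splicing was measured by RNA sequencing in HEK293T cells, a transformed human embryonic kidney line. Aurora-A, a kinase of the centrosome and mitotic spindle encoded by AURKA, was inhibited with MLN8237 (alisertib). In separate cells siRNAs depleted the SR proteins SRSF1, SRSF2, SRSF3 and SRSF7, which bind exonic sequences and promote splicing, the splicing factor RBM39, or SF3B5, a subunit of the SF3b complex that recognises branch points. The design asked for a functional link between Aurora-A and splicing regulators. The 20 samples form 10 groups of 2, and the authors' deposited tables list events by the mean PSI of each group, the percent of transcripts that include a segment. All PSI values of single events below are the authors' means, with no replicate error, and the depth behind them is unknown.

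MLN8237 had the shortest list, with 205 events in 194 genes. The lists held 2069 events for SRSF1, 2738 for SRSF2, 4245 for SRSF3, 1768 for SRSF7, 3946 for RBM39 and 11832 for SF3B5 depletion. The median absolute change was 18.6 points for MLN8237 (bootstrap 95% interval 17.8 to 19.2) and 25.4 points for SF3B5 (25.2 to 25.7), with the other depletions between 20.4 and 23.0 points. Changes of at least 25 points made up 12.7% of the MLN8237 list and 51.3% of the SF3B5 list. The authors' threshold truncates these sizes, and no test between tables was made.

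In the authors' deposited table for MLN8237, the highest gain was an alternative 5' splice site of BRCA1, a DNA repair gene, at 8.47% in DMSO and 61.9% in MLN8237. Alternative splice sites also led in DOK1 (39.0% and 86.6%), the antisense RNA gene TPT1-AS1 (33.7% and 75.5%), SYNE2, a nuclear envelope spectrin repeat gene (27.5% and 62.1%), and UBR4, a ubiquitin ligase (32.9% and 63.0%). Among exons, a 40-base exon of PFN1, which encodes the actin-binding protein profilin, was at 10.8% in DMSO and 37.2% in MLN8237.

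The largest loss under MLN8237 was a 145-base coding exon of the zinc finger gene ZNF35 at chromosome 3, 44652557 to 44652701, at 100% in DMSO and 27.9% in MLN8237. Lower inclusion was also listed for a 169-base coding exon of PRELID3A (60.3% and 28.3%; chromosome 18, 12420325 to 12420493), a 72-base exon of the cofilin phosphatase gene SSH3 (89.6% and 64.0%) and a 105-base exon of DCUN1D4 (73.0% and 49.2%). A 185-base exon of PKD1 was at 86.9% and 59.3%, and a 200-base exon of CROCC, the ciliary rootlet gene, at 64.5% and 40.1%. PKD1 and CROCC have near-identical pseudogene copies, so both are uncertain. Introns of the non-coding RNA genes HOXA-AS2 (87.9% and 52.4%) and SNHG12 (60.6% and 30.7%) and of XRRA1 (46.9% and 17.3%) were retained less. In the non-targeting siRNA controls, which received no MLN8237, the MLN8237 events that were also listed in a depletion table lay a median of 0.367 of the way from DMSO to MLN8237 in siNT1 (bootstrap 95% interval 0.203 to 0.563, 53 events) and 0.437 in siNT2 (0.315 to 0.493, 65 events).

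Few genes of the fixed lists had an MLN8237 event. Besides BRCA1 they were KMT2E, with a 74-base untranslated or non-coding exon at 19.0% and 40.2%, TET2, with a 3455-base coding exon at 64.0% and 82.7%, and the centrosomal gene CEP295, with a 144-base exon at 67.5% and 51.8%. No MLN8237 event lay in a gene of the SR protein, hnRNP, core spliceosome, splicing kinase, cell cycle, apoptosis, nonsense-mediated decay or 3' end processing lists. None of the 11 lists differed from the background for MLN8237 by Fisher's exact test; the smallest p was 0.265 unadjusted, for the mitosis list, and no list passed adjusted over the list alone. With 194 genes, intervals were wide, such as 0.0238 to 6.33 for the odds ratio of the hnRNP list. AURKA had no event under MLN8237.

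Under MLN8237, 57 cassette exons were higher and 57 were lower (50% lower, exact 95% interval 40.5 to 59.5). Retained introns were lower in 9 of 10 events (exact binomial adjusted p = 0.0251). Alternative 5' splice sites made up 19.5% of MLN8237 events against 4.32% of events elsewhere (odds ratio 5.37, 3.77 to 7.64, Fisher's exact adjusted p = 1.27e-14). Alternative 3' splice sites made up 16.6% against 6.20% (odds ratio 3.01, Fisher's exact adjusted p = 4.82e-07), while retained introns made up 4.88% against 13.6% (odds ratio 0.326, adjusted p = 1.45e-04). The shares elsewhere lean on the 11832 SF3B5 events. Among events not listed for SF3B5, alternative 5' splice sites made up 8.10%, alternative 3' splice sites 11.2% and retained introns 15.8%. At changes of at least 25 points, over 26 events, the odds ratio was 1.21 for retained introns and 2.74 for alternative 3' splice sites, and neither passed Fisher's exact test (adjusted p = 0.758 and 0.208).

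In SRSF1-depleted cells, exons were lost in HEMK1 (93.0% in siNT1 and 19.2% after depletion), RPS6KL1 (76.9% and 4.06%), IRF3, a transcription factor of the interferon response (78.5% and 7.80%), and the ciliary genes CEP290 (90.4% and 21.8%) and MKS1 (89.5% and 23.7%), per the authors' deposited table. The MKS1 exon of 134 bases is coding, at chromosome 17, 58207085 to 58207218. Exons of EYA4 (23.1% and 83.3%) and ZDHHC20 (15.9% and 67.8%) were included more. On the fixed lists, a 45-base exon of CIT, the citron kinase of cytokinesis, was at 9.72% and 56.4%, and a 472-base intron of RECQL5 at 33.8% and 76.3%. Of cassette exons, 978 of 1547 were lower (63.2%, 60.8 to 65.6, exact binomial adjusted p = 2.90e-25).

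In SRSF2-depleted cells the largest loss was a 146-base coding exon of HAUS4, a subunit of the augmin complex of spindle microtubules, at 94.3% in siNT1 and 4.54% after depletion (chromosome 14, 22947868 to 22948013). Lower inclusion was listed for OGFOD2 (85.9% and 8.36%), the spindle checkpoint gene MAD1L1 (88.9% and 30.8%), NEDD1, which recruits gamma-tubulin (83.9% and 34.3%), and FANCE of the Fanconi anaemia pathway (87.1% and 38.1%). A 60-base coding exon of STXBP5 was at 24.3% and 82.1% in the authors' deposited table. Of cassette exons, 1539 of 2066 were lower (74.5%, adjusted p = 1.21e-113), and 243 of 306 introns were higher (20.6% lower, exact binomial adjusted p = 7.55e-26).

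In SRSF3-depleted cells, exons were lost in HNRNPUL1 (96.8% in siNT2 and 5.10% after depletion), the acetyltransferase gene CREBBP (98.3% and 8.69%), RBM27 (99.4% and 10.9%) and PROSER1, whose listed exon has 1593 bases (91.8% and 3.40%). A 249-base coding exon of BRCA2 was at 98.8% and 24.6% (chromosome 13, 32319077 to 32319325), and a 240-base exon of the chromatin remodeller EP400 at 93.7% and 24.1%. The authors' deposited table also listed 3' splice sites of the translation factor gene EIF4A1 (4.4% and 88.8%) and RPS15A (5.84% and 87.3%), both in families with many copies. Of cassette exons, 2686 of 3295 were lower (81.5%, 80.1 to 82.8). Of introns, 120 of 265 were lower (45.3%, exact binomial adjusted p = 0.155).

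In SRSF7-depleted cells, exons were lost in RBCK1 (83.6% and 19.4%), the kinase gene PDK3 (95.8% and 35.0%), the clock gene PER2 (91.9% and 33.3%) and PTBP2, a splicing regulator (34-base coding exon, 61.8% and 20.3%; chromosome 1, 96806419 to 96806452). A 59-base exon of CLK4, a kinase of SR proteins, was at 14.7% and 48.8%, and an exon of N4BP2 at 21.5% and 78.1%, per the authors' deposited table. Of cassette exons, 1087 of 1365 were lower (79.6%, 77.4 to 81.7), and 115 of 162 introns were higher (exact binomial adjusted p = 1.29e-07).

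In RBM39-depleted cells, exons were lost in GK5 (86.7% in siNT2 and 13.4% after depletion), AUP1 (98.1% and 31.2%), MICAL1 (92.8% and 24.1%) and the histone deacetylase gene HDAC1, whose 93-base coding exon at chromosome 1, 32329068 to 32329160, was at 96.1% and 32.1%. Lower inclusion was listed for the splicing regulators RBM5 (89.7% and 38.6%) and TIA1 (72.0% and 24.3%), the caspase gene CASP9 (76.6% and 28.6%) and the gamma-tubulin complex gene TUBGCP4 (93.3% and 42.3%). A 24-base microexon of CSNK1G3 was at 17.6% and 82.9%, and an intron of ANKRA2 at 8.18% and 67.8%, in the authors' deposited table. Of cassette exons, 2454 of 2691 were lower (91.2%, 90.1 to 92.2), and 700 of 782 introns were higher (10.5% lower, exact binomial adjusted p = 2.81e-122). Introns made up 19.8% of the list against 11.9% elsewhere (odds ratio 1.83, Fisher's exact adjusted p = 4.54e-35). They made up 15.8% of events not listed for SF3B5, RBM39 events among them.

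In SF3B5-depleted cells, exons were lost in the cyclophilin gene PPIA (93.5% in siNT1 and 3.48% after depletion), IMPA1 (92.6% and 4.78%), PLK4, the kinase of centriole duplication (97.0% and 19.8%), NEDD1 (96.5% and 24.4%), the Fanconi anaemia genes FANCG (87.7% and 12.9%) and FANCD2 (86.6% and 14.9%), and EED of the Polycomb complex (92.9% and 21.1%). FANCI, singled out after its values were seen, had the most listed events, 28. PPIA has many processed pseudogenes, so its value is uncertain. An intron of PRPF40B was at 2.38% and 79.7% (chromosome 12, 49634093 to 49634331), per the authors' deposited table. AURKA itself was listed with 4 exons, each lower, among them a 98-base untranslated or non-coding exon at 24.0% and 5.38%, and a 139-base coding exon at 99.3% and 80.1%. Of 4 listed RBM39 exons 1 was higher, and a 72-base exon was lower after SF3B5 depletion (94.8% and 70.3%) and after SRSF3 depletion (88.0% and 72.4%), and a 111-base exon of SRSF7 was at 100% and 84.0% after SF3B5 depletion. Of cassette exons, 9440 of 9627 were lower (98.1%, 97.8 to 98.3), and 1330 of 1426 introns were higher (6.73% lower, exact binomial adjusted p = 2.33e-277). The median control PSI of all listed events was 95.1% for SF3B5, 78.8% for SRSF3, 70.6% for SRSF7 and 67.8% for RBM39. It was 67.4% for SRSF2, 59.0% for SRSF1 and 57.3% for MLN8237. Control PSI limits direction, so its part in these shares cannot be told apart from that of the treatment.

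**Figure D1:**
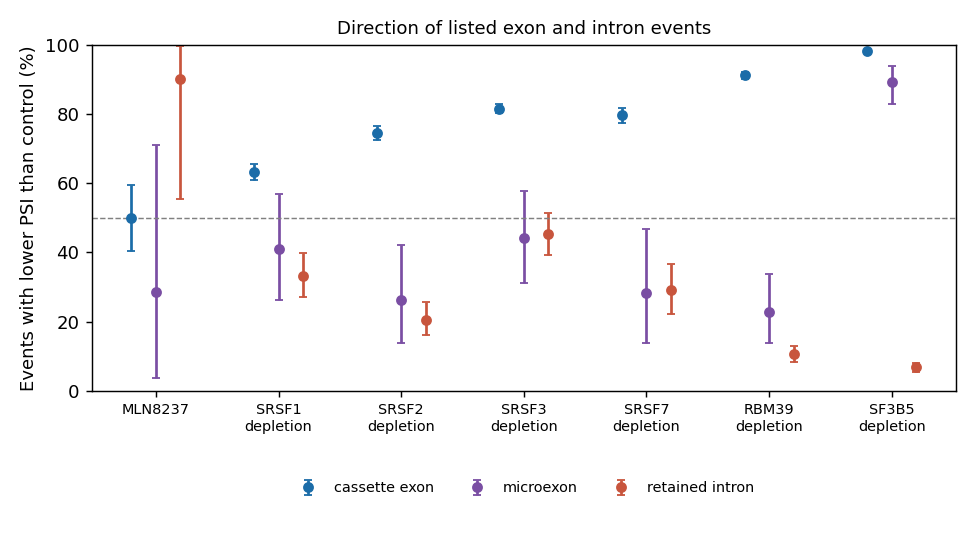
Percent of listed events with a lower PSI than control (y axis) for MLN8237 and the 6 depletions (x axis), by event type; points are shares and bars exact 95% intervals over events, with a dashed line at 50%. Cassette exons run from 50% lower for MLN8237 to 98.1% for SF3B5, and retained introns from 90% lower for MLN8237 to 6.73% for SF3B5. The shares also depend on control PSI, because events near full or no inclusion can be listed in a single direction only.

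Of the fixed lists, genes of mitosis, centrosome and spindle were over-represented after SF3B5 depletion. Of the 122 such genes with any event, 109 had one there (odds ratio 3.49, 1.96 to 6.21, Fisher's exact adjusted p = 1.15e-04, and 1.05e-05 adjusted over the list alone). In these genes 283 of 286 exons were lower and 32 of 32 introns were higher, PLK4 and NEDD1 among them, but the whole SF3B5 table was alike, with 9564 exons lower and 202 higher, and 1330 introns higher and 96 lower. Chromatin regulators were over-represented after SRSF3 depletion, with 55 of 95 genes (odds ratio 2.14, 1.42 to 3.22, Fisher's exact adjusted p = 0.0110, and 0.00200 adjusted over the list alone), including CREBBP and EP400. In these genes 62 of 79 exons were lower, in a table with 2712 exons lower and 642 higher. Within strata of exon number the chromatin odds ratio was 1.78 (Mantel-Haenszel chi-squared adjusted p = 0.203). At changes of at least 25 points it was 1.60 (Fisher's exact adjusted p = 0.352). Adjusted over the list alone, cell cycle genes also passed for SF3B5 (29 of 32) and, with fewer genes than the background, for SRSF7 (1 of 32), as did DNA repair genes for SRSF2 (32 of 78) and chromatin regulators for SRSF1 (32 of 95). Over all 77 tests each of those 4 had an adjusted p of 0.143, and no further list passed for any depletion, either way of adjusting.

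To relate Aurora-A inhibition to the splicing factors, events were matched between tables. Of the 205 MLN8237 events, 92 were in at least 1 depletion table, with 45 shared with RBM39, 40 with SRSF3, 22 each with SRSF1 and SF3B5, 19 with SRSF7 and 16 with SRSF2. The odds ratios below used only events also listed after a further depletion. For RBM39 that left 76 MLN8237 events, 29 of them shared, and for SRSF3 80, with 28 shared. The odds ratio was 3.97 for RBM39 (2.50 to 6.33), 3.97 for SRSF3 (2.50 to 6.31), 3.28 for SRSF1 (1.97 to 5.47) and 2.94 for SRSF7 (1.71 to 5.06), with Fisher's exact adjusted p of 2.41e-07, 2.41e-07, 7.68e-05 and 6.12e-04. It was 1.43 for SRSF2 (0.779 to 2.64, Fisher's exact adjusted p = 0.280) and below 1 for SF3B5 (0.484, 0.281 to 0.835, adjusted p = 0.00872). With 1 event per gene the SF3B5 value was 0.759 and no longer passed Fisher's exact test (adjusted p = 0.454).

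These overlaps depended on which events were compared. Over events with a control PSI of 20 to 80 the odds ratio was 0.963 for SRSF1 (0.508 to 1.83) and 0.895 for SRSF7 (0.438 to 1.83, Fisher's exact adjusted p = 1 for both). It was 2.42 for SRSF3 (1.38 to 4.24, Fisher's exact adjusted p = 0.0163) and 1.96 for RBM39 (1.12 to 3.43, adjusted p = 0.0404). The intervals of SRSF1 and SRSF7 overlap those of SRSF3 and RBM39, and no test compared the depletions. SRSF3 and RBM39 are also the only depletions compared with siNT2, in a sample set of their own. The depleted factor therefore cannot be told apart from the shared control or set here. Over all 7 tables as background, none of these 4 was past the threshold, with odds ratios of 1.00, 1.01, 0.857 and 1.09, while SF3B5 had 0.0739. That background includes events listed only in either of the compared tables. These lower the odds ratio by construction, so its values do not decide whether events are shared. At changes of at least 25 points none of the overlaps passed, each with 1 shared event in the background.

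**Figure D2:**
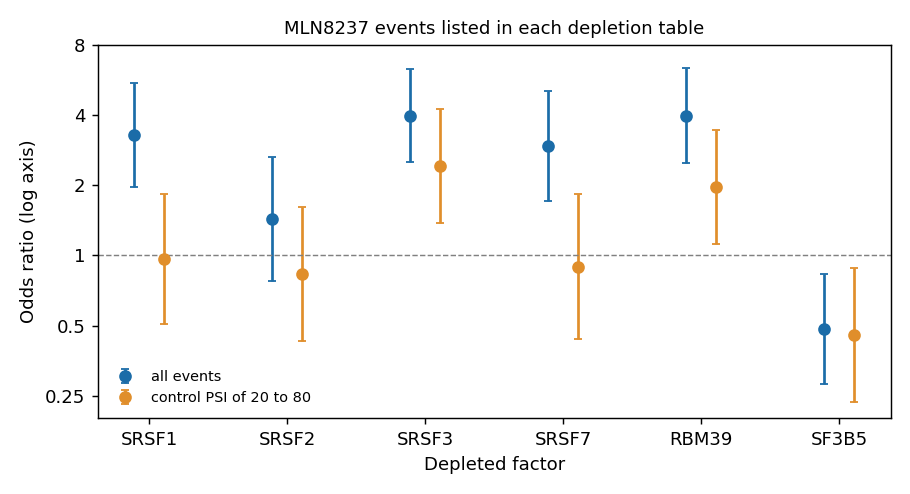
Odds ratio (y axis, log scale) of MLN8237 events being listed after each depletion (x axis), over all events and over events with a control PSI of 20 to 80; bars are 95% intervals and the dashed line marks 1. For SRSF1 and SRSF7 the value moves from 3.28 and 2.94 to 0.963 and 0.895, and for SRSF3 and RBM39, which share siNT2, both intervals lie above 1.

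A 185-base exon of PKD1 was lower under MLN8237 and after depletion of SRSF1 (78.8% in siNT1 and 19.9%), SRSF2 (44.3%), SRSF7 (30.9%), SF3B5 (45.1%) and SRSF3 (72.7% in siNT2 and 55.9%), where the siNT1 comparisons share their control. The ZNF35 exon was also lower after SRSF2 depletion (64.6% and 16.2%). With SRSF3, introns of HOXA-AS2 (69.1% and 35.1%), SNHG12 (51.2% and 30.0%) and XRRA1 (39.9% and 12.4%) and the exons of CROCC (46.7% and 26.5%) and DCUN1D4 (66.3% and 25.4%) were lower, as under MLN8237. Exons of C2CD3 (65.7% and 38.2%) and GUSBP11 (75.7% and 58.2%) were lower after SRSF3 depletion but higher under MLN8237; GUSBP11 belongs to the GUSB family of annotated pseudogenes, so its value is uncertain. The HOXA-AS2 intron was higher after RBM39 depletion (69.1% and 91.2%), opposite to MLN8237, per the authors' deposited tables.

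Among shared exons and introns, the direction was the same in 24 of 37 for SRSF3 (64.9%, 47.5 to 79.8), 13 of 17 for SRSF7, 11 of 14 for SRSF2, 11 of 17 for SRSF1, 19 of 41 for RBM39 (46.3%, 30.7 to 62.6) and 8 of 18 for SF3B5. None differed from an even split by the exact binomial test (smallest adjusted p = 0.172). Over all event types the shares were 67.5% for SRSF3 and 51.1% for RBM39, and the smallest adjusted p was 0.0638. For SRSF3, no shared exon or intron was lower under MLN8237 and higher after depletion, while 14 were lower in both, 10 were higher in both and 13 were higher under MLN8237 and lower after depletion (Fisher's exact test of the directions, chosen after the values were seen, adjusted p = 0.0336). That test did not pass for the other depletions.

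**Figure D3:**
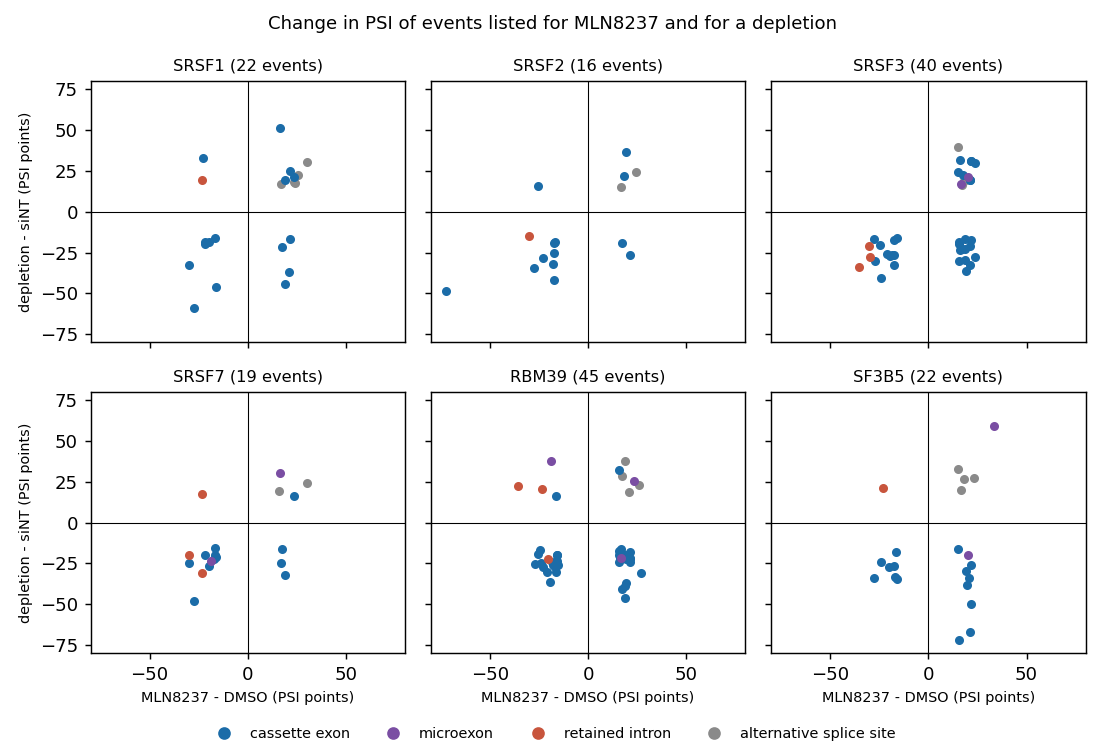
Change in PSI under MLN8237 (x axis, percentage points) against the change after each depletion (y axis, percentage points) for shared events; each point is 1 event, coloured by type, with no error. For SRSF3 the upper left quadrant is empty, and alternative splice sites lie only in the upper right because all are listed with a gain.

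Between depletions, events were shared above the background in each of the 15 pairs, with odds ratios from 1.48 for SRSF3 and SF3B5 to 6.69 for SRSF1 and SRSF7. Over events with a control PSI of 20 to 80 all 15 still passed, but the values ran from 1.48 for SRSF3 and SF3B5 to 2.95 for SRSF1 and SRSF7, and those of the 10 pairs without SF3B5 were lower by over 1.5 times. At changes of at least 25 points SRSF3 and SF3B5 had 1.07 and did not pass Fisher's exact test (adjusted p = 0.581). Among pairs with different control libraries, RBM39 and SF3B5 shared 1576 events, and 1461 of 1526 exons and introns had the same direction (95.7%, 94.6 to 96.7), against 81.2% from each list's own shares. Here and below, the lists' shares take no account of the control PSI of each event, which limits its direction in both lists. Agreement above them may come from control PSI, and no expectation matched for it was made. For SRSF3 and SF3B5 87.3% had the same direction against 79.4% from the lists' shares, and for SRSF2 and RBM39 75.0% against 59.9%. For SRSF1 and RBM39 it was 52.3% (48.0 to 56.6, exact binomial adjusted p = 0.301) against 52.4%. Over all event types that pair had 54.2% and did not pass the exact binomial test (adjusted p = 0.0520), nor did it with 1 event per gene (51.0%). It passed at changes of at least 25 points (63.2%) and without retained introns (55.0%). Those settings include alternative splice sites, all listed with a gain, so every shared site agrees by construction. Such passes therefore do not decide whether the directions of this pair agree. Of the 18 events listed after all 6 depletions, exons of GK5, FLAD1, FHL1 and of the separase gene ESPL1 were lower in each, and a 12-base microexon of the Hippo pathway transcription factor gene TEAD1 was higher in each, chosen after their values were seen. The other 13, such as exons of PTBP2, MFF and BIN1, went both ways.

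Pairs that share control libraries were set apart. With siNT1, the direction was the same in 83.3% of exons and introns for SRSF1 and SRSF7, 83.9% for SRSF2 and SRSF7 and 71.7% for SRSF1 and SRSF2, against 54.8%, 57.4% and 52.0% from the lists' shares. For SF3B5 it was 63.8% with SRSF1, 81.4% with SRSF2 and 81.6% with SRSF7, against 58.7%, 71.2% and 71.4%. With siNT2, it was the same in 79.5% for SRSF3 and RBM39, against 68.3%. In simulated unchanged groups with a shared control, 99.5% of events past the threshold in both had the same direction, but only about 101 of 19162 events were past it in both. In 1 such group 2.32% were past it, about 444 of 19162, which is more than the 205 events of MLN8237. The noise came from the 3392 events with a value in both siNT1 and siNT2, not from DMSO, and the number of events measured under MLN8237 is unknown. Because siNT1 and siNT2 belong to different sample sets, their difference includes any difference between sets. MLN8237 and DMSO share a set. The 3392 events were each listed after depletions of both sets and may vary more than the rest. The simulated counts can therefore overstate chance. They can also understate it, because the 19162 events are only those listed after a depletion, not all events measured. Whether the MLN8237 list exceeds chance is thus not decided by them. SRSF1 and SRSF7 shared 444 events against 191 for independent lists, with 142 higher in both against 32.6 and 234 lower in both against 63.8. SRSF3 and RBM39 shared 779 against 874, with 510 lower in both against 377. These expectations use listed events as the total, and by them 7 of the 15 pairs, among them the 5 with SF3B5, shared fewer events than independent lists would. A total without unlisted events raises each expectation by construction, so a shortfall against it does not decide whether events are shared. The control groups of 2 libraries could not be split, so the part of any excess that the shared controls account for was not measured.

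**Figure D4:**
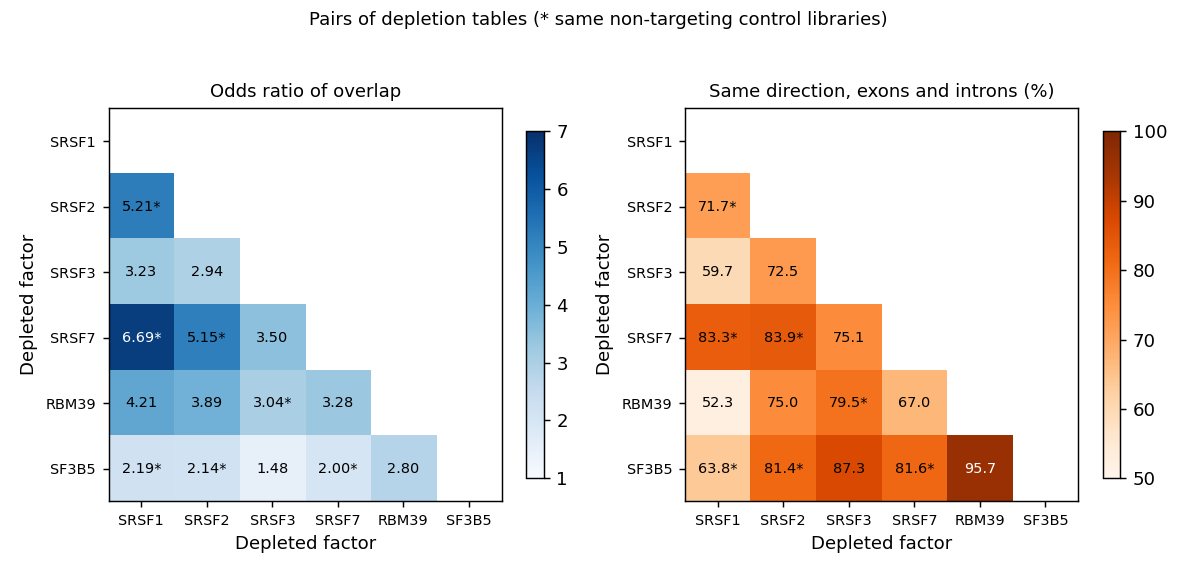
Odds ratio of overlap (left) and percent of shared exons and introns with the same direction (right) for each pair of depletions (both axes); stars mark pairs with the same control libraries. SRSF1 and SRSF7 have the highest odds ratio, 6.69 (2.95 over events with a control PSI of 20 to 80), and RBM39 and SF3B5 the highest share, 95.7%.

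Exons whose length is a multiple of 3, which keep the reading frame inside coding sequence, made up 48.2% of listed exons after SRSF1 depletion against 40.6% elsewhere (odds ratio 1.36, 1.23 to 1.51, Fisher's exact adjusted p = 5.37e-08). The odds ratio was 1.20 for SRSF2 and for RBM39, 1.23 for SRSF7 and 1.12 for SRSF3, each past the threshold, and 0.828 for SF3B5 (39.9% against 44.5%, Fisher's exact adjusted p = 3.95e-07). The share elsewhere leans on SF3B5, which had 9766 listed exons. Exons not listed for SF3B5 had 44.5%, near the 43.5% of SRSF3, 45.0% of RBM39, 45.3% of SRSF2 and 46.1% of SRSF7. Those exons come from these same depletions among others, so near values are partly built in. Values above 1 for these depletions may largely restate the contrast with SF3B5, but how far was not measured. For MLN8237 it was 1.14 (0.796 to 1.63, Fisher's exact adjusted p = 0.517).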

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

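The settings with exons and introns alone, with a control PSI of 20 to 80 and with strata of exon number were chosen after seeing the data. No paired analysis was possible because the tables give only group averages. For that reason leaving out each replicate, a replicate block and a filter on quality scores were not run, nor was overlap by coordinates. Of 285 values under alternatives, over 102 results, 230 kept their direction and side of the threshold or, for counts and sizes, stayed close, 1 of them at exactly 50% in the same direction, and 17 turned direction. Unless stated, the cause of a change was not tested.

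At changes of at least 25 points, which leaves 26 MLN8237 events, 38.5% of these were lower and SRSF1 reached 55.4%. The odds ratios with MLN8237 were 3.85 for SRSF1, 2.29 for SRSF3, 4.01 for SRSF7, 1.55 for RBM39 and 0.408 for SF3B5, none past the threshold with 1 shared event each in the background. SRSF3 with SF3B5 had 1.07, the same-direction share of SRSF1 with RBM39 was 63.2% and passed the threshold, the retained intron odds ratio of MLN8237 turned to 1.21, those of cassette exons to 0.869 for SRSF1 and 0.923 for SRSF2, those of alternative 3' splice sites to 1.28 for SRSF1, 1.09 for SRSF2 and 1.00 for SRSF7, and that of microexons to 0.881 for SRSF3, 16 rather than 27 tests of event type passed, and 1 rather than 2 gene list tests passed. Without retained introns, SRSF1 had 53.9% lower, and SRSF1 with RBM39 55.0% in the same direction, both past the threshold. The same-direction shares of SRSF1 with RBM39, 63.2% and 55.0%, include alternative splice sites, whose shared events agree by construction. They do not decide whether directions agree. With exons and introns alone, the MLN8237 share lower went from 33.2% to 51.9% and SRSF1 to 59.0%, since all alternative splice sites are listed with a gain, and the same-direction share with MLN8237 was 46.3% for RBM39 and 44.4% for SF3B5. With 1 event per gene, the odds ratio of MLN8237 with SF3B5 was 0.759 and no longer past the threshold, and the same-direction share of MLN8237 with RBM39 was 45.5%. By gene symbol, that with SRSF2 was 1.64 and past the threshold.

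With all 7 tables as background, the odds ratios with MLN8237 were 1.00 for SRSF1, 0.508 for SRSF2, 0.857 for SRSF3, 1.01 for SRSF7, 1.09 for RBM39 and 0.0739 for SF3B5, with SRSF2 and SF3B5 past the threshold. Events listed only in either of the compared tables enter that background and lower each value by construction. With a control PSI of 20 to 80 the odds ratio with MLN8237 was 0.963 for SRSF1, 0.833 for SRSF2 and 0.895 for SRSF7, and the overlaps between depletions ran from 1.48 to 2.95 rather than to 6.69, all past the threshold. Against all protein-coding genes 27 gene list tests passed, since genes with no listed event enter the background, and within strata of exon number 1 did. The median change of cassette exons alone was 17.7 points for MLN8237, 21.9 for SRSF1, 22.5 for SRSF2, 23.6 for SRSF3, 22.4 for RBM39 and 26.3 for SF3B5. The unknown depth limits all values of single events.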

Other observations

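The tests in this part were chosen after seeing the data, apart from the overlap with all 7 tables as background, the test of equal directions over all event types and the mitosis list without strata. Listed exons differed in length between depletions, in an order that depended on the direction. Exons lower after SRSF3 depletion had a median of 146 bases (bootstrap 95% interval 142 to 149, 2712 exons), such as those of PROSER1 and CREBBP, against 92 bases after SF3B5 depletion (91 to 93, 9564 exons), 98 after RBM39 depletion (96 to 100), and 115, 117 and 120 after SRSF1, SRSF7 and SRSF2 depletion. Exons higher after SF3B5 depletion had the longest median, 130.5 bases (115 to 147, 202 exons), against 85.5 after SRSF3 depletion (81 to 90, 642 exons) and 80 to 96 after the others. Introns higher after SF3B5 depletion had a median of 260 bases (233 to 288), those after SRSF3 depletion 284 (245 to 359) and after SRSF2 depletion 353 (300 to 448). The median was 571 after RBM39 depletion (467 to 660), 662 after SRSF7 depletion (501 to 878) and 868 after SRSF1 depletion (691 to 1136). For introns that were lower the order differed, with a median of 278 after SRSF1 depletion (219 to 410), 541.5 after SF3B5 depletion (420.5 to 714), 1057.5 after RBM39 depletion (535.5 to 1498.5) and 358 to 458.5 after the others.

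Microexons were higher more often than longer exons after each depletion, though not always in the majority. Control PSI limits direction and was not compared between microexons and longer exons. Its part in the odds ratios below therefore cannot be told apart from that of exon length. After RBM39 depletion 77.3% of 75 microexons were higher, CSNK1G3 among them, against 8.81% of 2691 longer exons (odds ratio 35.3, 20.2 to 61.6, Fisher's exact adjusted p = 8.43e-43, over 7 tables). The odds ratio was 9.99 for SRSF7, 8.23 for SRSF2, 6.11 for SF3B5, 5.60 for SRSF3 and 2.48 for SRSF1, each past the threshold, and 2.50 for MLN8237 (0.466 to 13.4, Fisher's exact adjusted p = 0.440, 7 microexons). After SF3B5 depletion 89.2% of 139 microexons were lower, and after SRSF1 and SRSF3 depletion microexons did not differ from an even split (exact binomial adjusted p = 0.314 and 0.457). Zinc finger genes, picked by symbol, made up 9.28% of MLN8237 genes, such as ZNF35, against 3.60% elsewhere (odds ratio 2.74, Fisher's exact adjusted p = 0.00118). Genes not annotated as protein-coding, such as TPT1-AS1 and SNHG12, made up 8.15% against 2.01% (odds ratio 4.33, Fisher's exact adjusted p = 4.41e-05, over 14 tests). Both groups were also over-represented for SRSF3, with odds ratios of 1.48 and 1.58 (Fisher's exact adjusted p = 0.00485 and 0.0157), and under-represented for SF3B5, with 0.510 and 0.227. Among genes with no SF3B5 event, they made up 5.66% and 4.80%, so the shares elsewhere lean on SF3B5.

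The MLN8237 events were also looked up in the non-targeting siRNA controls, which received no inhibitor and give a value only for events listed in a depletion table with that control. With DMSO at 0 and MLN8237 at 1, siNT1 lay at a median of 0.367 (0.203 to 0.563, 53 events) and siNT2 at 0.437 (0.315 to 0.493, 65 events), whereas depletion events read in the other non-targeting control lay between -0.0224 for SF3B5 and 0.0537 for RBM39. A difference between sample sets unrelated to MLN8237 would put the median of the MLN8237 events at 0 if it moved events equally both ways. Their siNT1 and siNT2 intervals lay above 0, although the 28 events higher under MLN8237 gave an siNT1 interval that includes 0 (0.419, -0.185 to 0.709). Events near full inclusion in DMSO, such as the ZNF35 exon at 100%, can differ only toward MLN8237. The events were also selected by their listing after a depletion. Intervals above 0 therefore do not decide against a set difference. Chance variation of the group means would put the median at 0.5, which stays open: the siNT1 interval includes 0.5 but that of its lower events does not (0.237 to 0.490), and the siNT2 interval excludes 0.5 but that of its exons and introns does not (0.360 to 0.523). A simulated unchanged group had about 444 of 19162 events past the threshold against 205 listed for MLN8237. Its noise includes any difference between the sample sets of siNT1 and siNT2, so that count does not decide the question. A mixture of chance and real events may be present, and a shared response to transfection and to Aurora-A inhibition was not tested.

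The overlap of MLN8237 with the depletions may have more than 1 source. If it came from events of intermediate inclusion being listed more often, it should vanish among events with a control PSI of 20 to 80. There the odds ratio was 0.963 for SRSF1 (0.508 to 1.83) and 0.895 for SRSF7 (0.438 to 1.83), both intervals including 1. For SRSF3 (2.42, 1.38 to 4.24) and RBM39 (1.96, 1.12 to 3.43) the intervals lay above 1. The intervals of SRSF1 and SRSF7 overlap these and rest on few shared events. A difference between the depletions was not tested. SRSF3 and RBM39 share the siNT2 libraries and a sample set, so they are not separate results on this point. Listing of variable events by chance stays open for all 4. The association of directions had a Fisher's exact adjusted p of 0.502 for SRSF1, 0.0336 for SRSF3, 0.382 for SRSF7 and 0.795 for RBM39, but it was chosen after the SRSF3 counts were seen, and the test of equal directions did not pass for SRSF3 (exact binomial adjusted p = 0.0770 over all event types and 0.198 over exons and introns). With all 7 tables as background, the SRSF3 overlap was not past the threshold (0.857), but that background lowers the odds ratio by construction, so this value does not decide.

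Mitosis genes in the SF3B5 table have many exons, with a median of 20 on the list against 12 in the background, and so more events to list. Within strata of exon number the odds ratio was 2.78 (1.55 to 5.00, Mantel-Haenszel chi-squared adjusted p = 0.0449), down from 3.49, which argues against exon number as the whole cause. Expression level, which decides whether an event can be measured, was not tested.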
